A study of Neurospora crassa with 8 samples.

How the data were processed

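The libraries were made from poly(A) RNA of Neurospora crassa, a filamentous ascomycete, grown as shaken liquid cultures for 48 hours at 32 degrees C in a minimal medium with 1.5% sucrose. Wild type and the ve-1 mutant were each grown in the standard medium and in the same medium prepared without iron, with 2 cultures in each of the 4 groups. Groups and replicate numbers were taken from the sample labels.

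The per-library values were raw read counts per gene as deposited by the authors, with no normalization. FastQC, Trim Galore and STAR are named in the submitters' processing notes, with no version or role, and a stranded mRNA library kit is named in the labels' protocols. The counting tool, the strand setting, the genome build and the annotation release are not given in the sources used here. The authors also deposited 4 tables of their own comparisons, with log2 fold changes and adjusted p-values, and DESeq2 is named in the submitters' processing notes. Those tables list only genes with an adjusted p under 0.05, and their log2 fold changes look shrunken beside the group means printed next to them. They were used only to count shared genes and signs.

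Gene symbols came from a table of the RefSeq annotation of assembly NC12, which matched 9729 of the 9730 gene identifiers. Because the authors' build is not named, that table served only for names, gene spans and the order of neighbouring genes, and no coordinates are printed. It holds symbols for 1089 of the 8118 tested genes and no product descriptions. NCU02775, NCU05964, NCU00646 and NCU01033 have no symbol in it and are given by locus; before the data were examined they had been entered in the gene lists under ve-2, vos-1, lae-1 and wet-1. Of 167 named genes, 38 overlap another annotated gene, so their counts are uncertain without a stated strand setting. Those named below are NCU05883, NCU05964, NCU10015, NCU10016, cao-1, cdt-1, con-6, fwd-1, ncw-1, nuo10.4, pks-5 and tre-1.

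Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 8118 genes. TMM factors scaled the libraries, and all 8 libraries were fitted together as 4 groups with robust quasi-likelihood dispersions and 4 residual degrees of freedom. Contrasts were tested with the quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05. The contrasts were ve-1 against wild type in each medium, iron-free against standard medium in each genotype, and the difference of the differences (the interaction). Levels are TMM-normalised CPM, given as mean ± SD over 2 libraries, and standard errors were taken as the log2 fold change divided by the square root of F. Adjusted p values given below for single genes come from this edgeR test.

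Genes to be named were fixed by a rule written before the data were examined. Among called genes whose libraries did not overlap between the groups and whose higher group had a mean of at least 50 normalised counts, the rule took the 8 largest rises and falls with a symbol and the 2 largest rises and falls with or without one. It added up to 4 called members of every gene list, and all members of the velvet, carotenoid, and light and clock lists. For the interaction it took the 5 highest and 5 lowest called genes. With 2 libraries against 2, chance gives non-overlapping groups for 33.3% of genes. Where both libraries of a group held 0 counts, a fold is given as a bound against 3 counts over the group. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

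In all, 27 gene lists were fixed before the data were examined, defined by symbols and, where the annotation gave them, product words. The 18 lists with at least 3 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over lists within a contrast. They were velvet, carotenoid, light and clock, conidiation, sexual development, respiratory chain, secondary metabolism backbone, ergosterol, cytoplasmic ribosome, heat shock and chaperones, oxidative stress, plant cell wall degradation, fungal cell wall, histones, proteasome, heterokaryon incompatibility, sugar transport and amino acid transport. The mating type, siderophore and iron uptake, TCA cycle, cytochrome P450 and other metal transport lists held 1 or 2 tested genes. The lists for iron-sulfur and heme synthesis, ribosome biogenesis, the mitochondrial ribosome and peptidases held no gene, because they depended on product words, so those functions were not analysed here. The sexual development list includes ham genes, known from hyphal fusion; the respiratory list includes cyt genes that act in mitochondrial RNA splicing and not in a complex; the plant cell wall list takes all glycoside hydrolase symbols, among them chitinase families. The conidiation list marks asexual spores, another cell type that a culture can hold.

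The procedure was tested on simulated counts for the 8118 genes, with 50 genes changed at each of 4 fold sizes. For ve-1 against wild type in standard medium, 8% of genes changed 2-fold, 78% of those changed 4-fold and 96% of those changed 16-fold were recovered, with 7 false calls. The corresponding shares were 10%, 68% and 94% for the mutant effect in iron-free medium, with 10 false calls. They were 2%, 72% and 94% for the iron effect in wild type and 10%, 72% and 90% for the iron effect in ve-1, with 6 false calls in each. For the interaction they were 2%, 26% and 78%, with 7 false calls. The simulated counts were drawn for each gene separately, with the dispersions of the fit. They held no co-variation of genes between cultures and no strain difference, so the false calls are not an error rate for these libraries.

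The alternatives tried were total-count, upper-quartile and RLE scaling, no low-count filter, DESeq2 1.42.0, limma-voom, counts thinned to the smallest library, the replicate number as a block, fits on only the 4 libraries compared, and each of the 8 libraries left out in turn, in which case the lone library of its group was assumed to vary like the other groups. For the lists they were a correlation estimated per list and fry. A fit with 1 library left out also has fewer residual degrees of freedom, so a lost call can reflect lower power as well as that library. A gene-length correction, correlations without single libraries, list counts and runs of neighbours without single libraries, the velvet list without ve-1, and tests of gene families named by symbol stem were added after seeing the data. Figures were drawn with Python 3.11.15.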

Results

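Poly(A) RNA was sequenced from 8 shaken cultures of Neurospora crassa, 2 for each combination of genotype (wild type or the ve-1 mutant) and medium (standard or iron-free). The title of the series names the velvet complex in development, secondary metabolism and light-dependent carotenoid synthesis, and the layout asks how loss of the velvet regulator VE-1 and absence of iron change transcript levels, alone and together. Total counts per library ran from 6654585 to 10192729, and 8118 genes were tested. The 10 most abundant genes took from 7.9% (Wilson 95% interval 7.84 to 7.88) of counts, in wild-type iron-free replicate 1, to 18.6% (18.52 to 18.58), in wild-type standard replicate 1. TMM factors ran from 0.774 to 1.257. Replicates of a group differed by far more than counting noise (chi-square per degree of freedom of 39.3 to 171.2), so no pair of libraries looked like 1 library deposited 2 times. The first 2 principal components of log2 CPM held 48.6% and 28.7% of the variance.

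Transcripts of ve-1 (NCU01731) followed the labels in every library. The gene had 1077, 1533, 2977 and 1931 counts in the wild-type libraries and 20, 28, 15 and 80 in those of ve-1. In standard medium its level was 193 ± 53.6 CPM in wild type and 3.6 ± 1.14 in ve-1 (SD, n = 2), a log2 fold change of -5.75 (SE 0.63, adjusted p = 0.003761); without ve-1 standard replicate 1 the adjusted p was 0.0527. In iron-free medium the levels were 247 ± 30.4 and 4.09 ± 3.3 CPM (log2 fold change -5.88, SE 0.62, adjusted p = 0.003961). The GATA factor gene sre (NCU07728), whose product is known to repress siderophore synthesis, was at 145 ± 39.5 CPM in wild type with iron and 10.6 ± 3.51 without it, and at 171 ± 28.6 and 7.62 ± 0.475 CPM in ve-1. The mating-type gene matA-1 (NCU01958) differed within groups. It had 118 and 0 counts in the wild-type standard libraries, 0 and 403 in those of ve-1, 74 and 0 in the wild-type iron-free libraries, and 1 and 5 in those of ve-1; it was not called in any contrast. The other 2 mating-type genes listed were not tested.

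In standard medium, 4 of 6 genes of vegetative incompatibility and 5 of 9 ham genes of hyphal fusion were lower in ve-1, and 6 of 10 cys genes of sulfur metabolism were higher. As groups these passed camera but not with an estimated correlation (adjusted p = 0.4368, 0.875 and 0.875), and the ham and cys families were chosen after the data had been seen. The largest falls were in NCU05126, from 820 ± 527 CPM to 0.297 ± 0.0254 (log2 fold change -11.37, SE 0.99, adjusted p = 0.002429), and in NCU05567, from 793 ± 479 to 0.357 ± 0.283 CPM (SD, n = 2). Of the 4 velvet-list genes, ve-1 fell, NCU05964 fell with a log2 fold change of -7.96 (SE 0.92), NCU02775 fell with -1.76 (SE 0.23), and NCU00646 rose with 2.12 (SE 0.59). The 4 heterokaryon incompatibility genes that fell were the transcription factor gene vib-1 (log2 fold change -3.71), tol (-4.67), pin-c (-3.95) and het-6 (-3.69). The sulfate permease gene cys-14 rose from 17.2 ± 6.67 to 350 ± 229 CPM and the arylsulfatase gene ars-1 from 0.591 ± 0.0183 to 22.2 ± 10.5 CPM. The gene cys-16 rose with a log2 fold change of 5.27 (SE 0.44). NCU07820 and NCU09039 had 0 counts in both wild-type libraries and were at least 718-fold and at least 556-fold higher in ve-1. Other falls included the potassium transporter gene hak-1 (-3.94), the cell wall protein gene ncw-1 (-3.88), asd-1, a gene of ascus development (-3.61), the meiotic gene msh4 (-3.91) and the hyphal fusion gene ham-9 (-2.77). Of the 67 named calls of this contrast, 9 held without any 1 library (pin-c, cys-14, cys-16, ars-1, NCU05126, NCU05567, NCU05964, NCU07820 and NCU09039). Each of the others was lost in at least 1 fit with a library left out. Most losses came without ve-1 standard replicate 1, then wild-type standard replicate 2, ve-1 standard replicate 2 and wild-type standard replicate 1.

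In all, 2258 of 8118 genes were called for ve-1 against wild type in standard medium, 1012 higher and 1246 lower, and 1884 of them changed at least 2-fold. With total-count scaling the split was 1541 higher and 787 lower, with the median of all genes moved by 0.31 on the log2 scale, and with upper-quartile scaling it was 1221 and 1009, with a shift of 0.13; changes are given relative to the TMM scaling. The number called fell to 104 without ve-1 standard replicate 1, to 538 without wild-type standard replicate 2 and to 796 without ve-1 standard replicate 2.

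**Figure D1:**
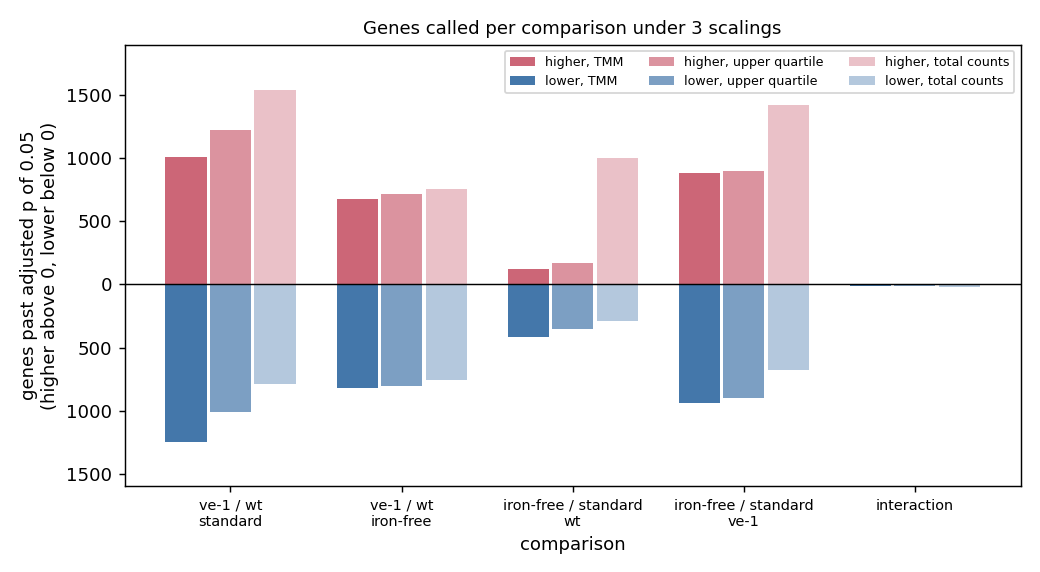
Number of genes called (adjusted p under 0.05) in each of the 5 contrasts under 3 library scalings, with genes higher above 0 and genes lower below 0. With TMM scaling, 119 genes were higher and 414 lower in wild type without iron, against 1003 and 287 with total counts; the bars of the interaction stand for 7 and 13 genes with TMM scaling and are hard to see at this scale.

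Subunits of respiratory complex I moved together in this contrast. Of the 43 respiratory chain genes, 24 fell and 3 rose (25 and 3 adjusted over the list alone), and all 24 that fell were among the 29 nuo genes, which encode complex I subunits. The median log2 fold change of the nuo genes was -1.25 and that of the other 14 members 0.25; nuo29.9 went from 244 ± 34.2 to 71.6 ± 19.4 CPM (SD, n = 2). The rises included cyt-4, a gene of mitochondrial RNA processing (log2 fold change 1.75, SE 0.34). The list was lower than other genes in camera (adjusted p = 0.0006477), as were the velvet list (adjusted p = 0.007036; 3 of 4 members lower and 1 higher, the same adjusted over the list alone; adjusted p = 0.1666 with ve-1, the mutated gene, left out of the velvet list, a test added after seeing the data) and the heterokaryon incompatibility list (adjusted p = 0.0006477; 4 of 6 lower, 5 adjusted over the list alone). With an estimated correlation none of the 3 calls held, with adjusted p = 0.7211, 0.4368 and 0.4368. Without ve-1 standard replicate 1 no respiratory member was called, and 1 incompatibility and 1 velvet member were called lower; without wild-type standard replicate 2 only 2 respiratory members were called lower. The 3 calls of whole lists held without any 1 library.

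The carotenoid and light genes named by the series title were in part called in standard medium, where 27.8% of all tested genes were. Of the 6 genes on the carotenoid list only cao-1 was called (log2 fold change -4.49, SE 0.85, adjusted p = 0.01221, and 1 adjusted over the list alone). It was listed by its symbol, and whether it acts in carotenoid synthesis was not settled here. The cao-1 call was lost without wild-type standard replicate 2 or ve-1 standard replicate 1. The phytoene synthase gene al-2 was at 503 ± 533 CPM in wild type and 382 ± 237 in ve-1, and the phytoene dehydrogenase gene al-1 at 665 ± 615 and 659 ± 627. The photoreceptor gene vvd was at 662 ± 652 and 625 ± 119 CPM (log2 fold change -0.08, SE 1.22, adjusted p = 0.9667), so that a change of several-fold either way was not detectable with this spread. Of the 11 light and clock genes, 3 rose (the opsin gene nop-1, frh and phy-1, with log2 fold changes of 2.65, 1.19 and 1.07) and 3 fell (phy-2, fwd-1 and sub-1, with -1.47, -1.41 and -0.98), the same numbers adjusted over the list alone. None of these 6 calls held without every library in turn. The clock gene frq was at 230 ± 9.74 and 229 ± 6.51 CPM, and wc-1 and wc-2 were not called.

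Genes on the conidiation list went both ways in standard medium, and all 4 members called lower were ccg genes. None of the 9 ccg genes was called higher. Of 22 members, 3 rose and 4 fell (4 and 5 adjusted over the list alone): con-6 rose from 164 ± 120 to 3720 ± 2110 CPM, while ccg-14 fell from 22800 ± 5350 to 1710 ± 182 CPM. The hydrophobin gene eas, the most abundant conidial marker on the list, varied within the wild-type standard and ve-1 iron-free groups. In each medium eas was higher in both ve-1 libraries than in both wild-type libraries. Its level was 53740 and 9323 CPM in the wild-type standard libraries, 91780 and 101200 in those of ve-1, 1253 and 1073 in the wild-type iron-free libraries, and 51530 and 2485 in those of ve-1. The con-6 call was lost without wild-type standard replicate 2 or either ve-1 standard library, and the ccg-14 call without ve-1 standard replicate 1, where no conidiation gene was called; without ve-1 standard replicate 2, 1 rose and 2 fell. Of the other lists, sexual development had 2 members higher and 8 lower of 26 (4 and 8 adjusted over the list alone), plant cell wall degradation 9 and 19 of 74 (10 and 22), fungal cell wall 1 and 8 of 26 (5 and 11), secondary metabolism backbone 2 and 0 of 6 (3 and 1), and cytoplasmic ribosome 2 and 0 of 7 (3 and 0). Members lower only were counted for ergosterol, 2 of 3 (2 alone), histones, 3 of 9 (3 alone), proteasome, 4 of 23 (2 alone) and sugar transport, 1 of 3 (2 alone). The oxidative stress list had 1 lower of 8 (0 alone), the heat shock list 1 higher and 1 lower of 11 (0 and 0 alone), and amino acid transport 0 of 4 (0 alone). None of these lists, nor the carotenoid, light and clock or conidiation list, passed camera, with adjusted p from 0.1666 to 0.9178. Of the short lists, the P450 gene cyp450-31 and the zinc transporter gene tzn-2 fell (log2 fold changes -2.08 and -1.51), and the citrate synthase gene cit-1 was not called.

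**Figure D2:**
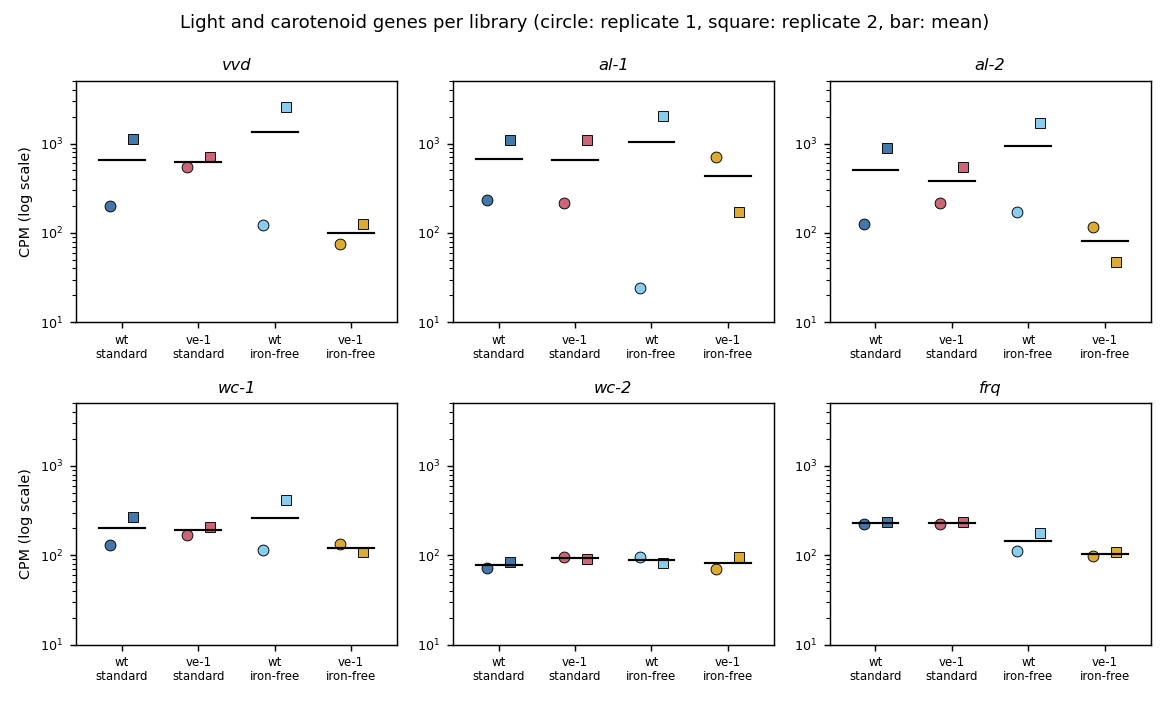
Level (CPM, log axis) of 6 light and carotenoid genes in each library, with the bar at the group mean of 2 libraries. In wild type without iron, vvd was at 122.6 CPM in replicate 1 and 2583 in replicate 2, while wc-2 lay within 77.6 to 93.2 CPM in all 4 group means.

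In iron-free medium, 5 of 6 acu genes of acetate use and 9 of 16 tca genes of the tricarboxylic acid cycle were higher in ve-1 than in wild type. Both families were chosen after the data had been seen, and neither passed with an estimated correlation (adjusted p = 0.694 for each). The conidial marker eas was at 1253 and 1073 CPM in the wild-type libraries and at 51530 and 2485 CPM in those of ve-1, and it was not called (adjusted p = 0.06274). The phosphoenolpyruvate carboxykinase gene acu-6 was at 320 ± 132 CPM in wild type and 6210 ± 3070 in ve-1 (SD, n = 2; log2 fold change 4.28, SE 0.89, adjusted p = 0.01971). The glyoxylate cycle genes acu-3 (isocitrate lyase) and acu-9 (malate synthase) rose with log2 fold changes of 3.48 and 3.80. The citrate synthase gene cit-1 rose from 398 ± 29.3 to 2060 ± 10.7 CPM, the cytochrome c gene cyc-1 from 5.23 ± 1.28 to 104 ± 41.1, the Rieske protein gene fes-1 from 56 ± 1.03 to 216 ± 5.17 and the chaperonin gene hsp60 from 93.9 ± 8.64 to 603 ± 81.7. The trehalase gene tre-1 rose with a log2 fold change of 5.07 (SE 0.88). Falls recurred in the incompatibility and fusion genes, with pin-c at -6.45 (SE 0.46), vib-1 at -2.70, het-6 at -3.53, ham-7 at -3.14 and ham-8 at -3.08. The polyketide synthase gene pks-5 was at 749 ± 1040 CPM in wild type and 0.711 ± 0.324 in ve-1 (log2 fold change -10.06, SE 2.17); the wild-type libraries were at 15.34 and 1482 CPM. NCU09640 had 0 counts in both ve-1 libraries and was at least 603-fold lower there. Of 53 named calls, 22 held without any 1 library, including ve-1, cit-1, cyc-1, fes-1, pin-c, het-6, vib-1, ham-7 and ham-8. Losses came to 23 without wild-type iron-free replicate 2, 21 without wild-type iron-free replicate 1, 19 without ve-1 iron-free replicate 2, 16 without ve-1 iron-free replicate 1, 7 without either ve-1 standard library and 1 without either wild-type standard library.

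This contrast called 1500 genes, 679 higher and 821 lower, of which 1350 changed at least 2-fold; edgeR on only the 4 libraries compared called 923. Left-out libraries took the number to 658 and 738 (wild-type iron-free replicates 1 and 2), 860 and 586 (ve-1 iron-free replicates 1 and 2), and 976 and 964 (ve-1 standard replicates 1 and 2).

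Of the gene lists, sexual development was lower in camera (adjusted p = 0.00441), with 8 of 26 members lower and 1 higher (8 and 1 adjusted over the list alone). That list takes in the ham genes of hyphal fusion, and 6 of 9 ham genes fell here. Its call therefore cannot be read as sexual development alone. The heterokaryon incompatibility list was lower too (camera adjusted p = 0.0001878), with 4 of 6 lower (5 adjusted over the list alone). Neither held with an estimated correlation (adjusted p = 0.3599 for each). The members of the former that fell included the hyphal fusion genes ham-7, ham-8 and ham-9, asd-1 and msh4, and their number was 5 without wild-type iron-free replicate 2 or ve-1 iron-free replicate 2; the incompatibility members that fell were pin-c, het-6, vib-1 and tol, and tol was no longer called without 6 of the 8 libraries. In the respiratory chain list 9 of 43 members rose and none fell (10 and 0 adjusted over the list alone), the list did not pass (adjusted p = 0.05847), and the median of the nuo genes was 0.01; the number that rose was 4 without either wild-type iron-free library or ve-1 iron-free replicate 2 and 6 without either ve-1 standard library. Of the 6 carotenoid genes only cao-1 was called (log2 fold change -3.03, SE 0.72; 1 lower adjusted over the list alone), and it was not without either wild-type iron-free library or ve-1 iron-free replicate 2; of the 11 light and clock genes none was (0 adjusted over the list alone). vvd was at 1350 ± 1740 CPM in wild type and 101 ± 37.5 in ve-1 (log2 fold change -3.75, SE 1.36, adjusted p = 0.09725), and al-2 at 928 ± 1070 and 81.4 ± 48.6 (adjusted p = 0.101). The velvet list, with 2 of 4 members lower and 1 higher, did not pass camera in this medium (adjusted p = 0.0618). Nor did plant cell wall degradation, with 17 of 74 members lower and 2 higher (camera adjusted p = 0.07043).

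Across the tested genes, the effect of ve-1 in standard medium and that in iron-free medium had a Pearson r of 0.60 and a Spearman rho of 0.55, over contrasts that share no library; genes are not independent replicates, so no p is given. Without wild-type standard replicate 2 the r was 0.45. Calls in both media numbered 233 higher and 508 lower, where independent lists would share 84.6 and 126, and 17 genes were called in opposite directions, where independent lists would share 206.6.

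**Figure D3:**
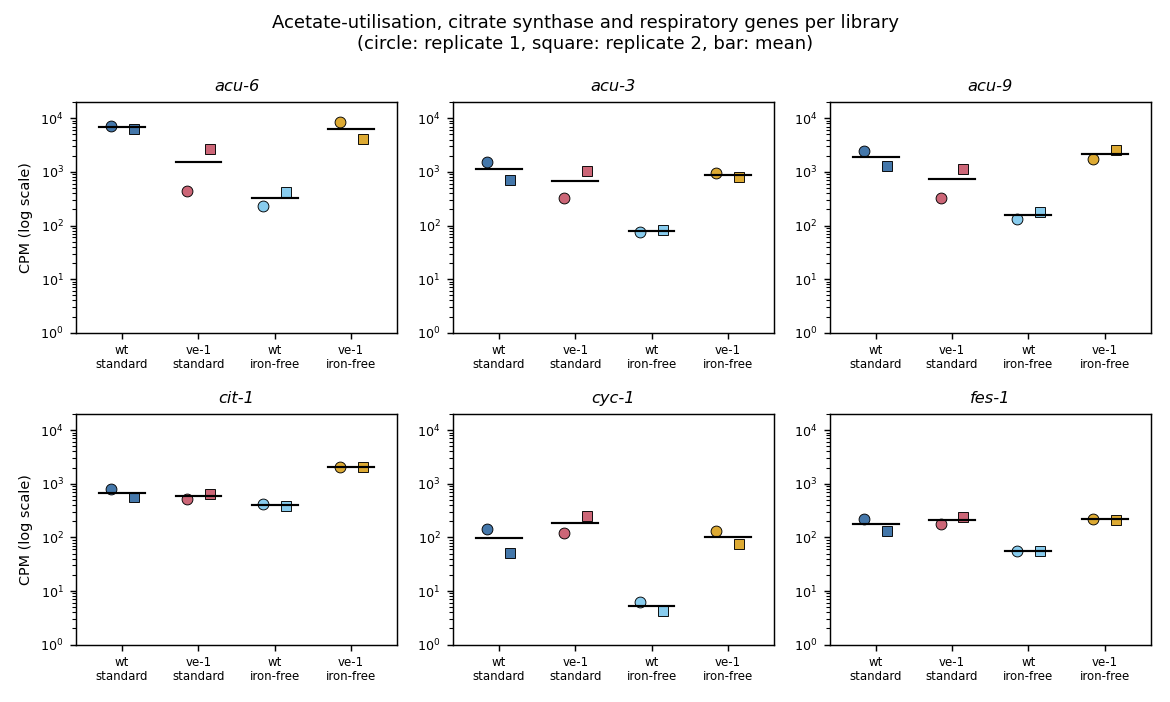
Level (CPM, log axis) of 6 genes of carbon use and respiration in each library, with the bar at the group mean of 2 libraries. In iron-free medium acu-6 averaged 320 CPM in wild type and 6210 in ve-1, and cyc-1 averaged 5.23 and 104.

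Absence of iron in wild type lowered 2 of 3 sugar transport genes, 2 of 8 oxidative stress genes, 5 of 16 tca genes and 6 of 22 conidiation genes, and raised 2 of 3 ergosterol genes. As groups these passed camera but not with an estimated correlation (adjusted p = 0.1006 for sugar transport, 0.97 for the tca family, which was chosen after the data had been seen, and 0.3461 for the others). sre fell with a log2 fold change of -3.77 (SE 0.34, adjusted p = 0.005857). The cellodextrin transporter genes cdt-2 and cdt-1 fell with log2 fold changes of -6.29 (SE 0.43) and -3.27 (SE 0.67). The catalase gene cat-1 fell from 2040 ± 63.7 to 121 ± 5.67 CPM and the mitochondrial superoxide dismutase gene sod-2 from 360 ± 90.4 to 63.7 ± 3.37 (SD, n = 2). cyc-1 fell from 97.5 ± 65.6 to 5.23 ± 1.28 CPM and acu-6 from 6740 ± 583 to 320 ± 132. tca-11 and tca-12 fell with log2 fold changes of -5.35 and -4.12. The wild-type iron-free libraries behind these falls also enter the mutant effect in iron-free medium, so the results are not independent. The sterol reductase gene erg-3 rose from 139 ± 29 to 922 ± 401 CPM and erg-1 from 60.7 ± 4.91 to 241 ± 134. Rises also included the laccase gene lacc (log2 fold change 3.56), arg-4 of arginine synthesis and NCU05089, from 8.48 ± 9.14 to 245 ± 67.6 CPM. Of the 40 named calls only sre and cdt-2 held without any 1 library. The others fell away with single libraries: 38 without wild-type iron-free replicate 2, 30 without wild-type standard replicate 1, 27 without wild-type iron-free replicate 1, 13 and 11 without ve-1 standard replicates 1 and 2, 11 without wild-type standard replicate 2, and 1 and 2 without ve-1 iron-free replicates 1 and 2.

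The contrast called 533 genes, 119 higher and 414 lower, of which 508 changed at least 2-fold. With total-count scaling it called 1290, with 1003 higher and 287 lower and the median of all genes moved by 0.52; upper-quartile scaling gave 170 and 350, with a shift of 0.11. The number depended on the libraries: it was 7 without wild-type iron-free replicate 2, 137 without wild-type iron-free replicate 1, 83 without wild-type standard replicate 1, and 228 and 240 without ve-1 standard replicates 1 and 2. DESeq2 called 1249 on all libraries and 1088 on the 4 compared, where edgeR called 130.

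In camera, 5 lists were lower: conidiation (adjusted p = 7.473e-06; 6 of 22 members lower, 11 adjusted over the list alone), sugar transport (adjusted p = 1.424e-06; 2 of 3, 3 alone), oxidative stress (2 of 8, 5 alone), heat shock and chaperones (3 of 11, 6 alone) and fungal cell wall (6 of 26 lower and 1 higher, 8 and 1 alone). The last 3 each had an adjusted p = 0.006309. The ergosterol list was higher (adjusted p = 0.02351; 2 of 3 members, 2 adjusted over the list alone), and it was not without wild-type standard replicate 1 (adjusted p = 0.06137) or replicate 2 (adjusted p = 0.1025). With an estimated correlation no list passed, with adjusted p = 0.1006 for sugar transport and 0.3461 for each of the others. The median of the fungal cell wall list was -0.60, and -0.11 with total-count scaling. Of the 6 conidiation members that fell, 5 were ccg (clock-controlled) genes, among them ccg-14 (log2 fold change -3.30), ccg-13 (-3.15) and ccg-9 (-2.92). The level of eas, given above, was lower in both iron-free libraries than in both standard libraries, but eas was not among the calls. Heat shock members that fell were hsp78, hsp70-1 and hsp98. Without wild-type iron-free replicate 2 no conidiation, cell wall, heat shock, oxidative stress or ergosterol member was called. Without wild-type iron-free replicate 1 the members lower were 1 for conidiation, 1 for cell wall and 0 for heat shock and oxidative stress, and without wild-type standard replicate 1 they were 1, 1, 0 and 1. Without wild-type standard replicate 2 or either ve-1 standard library 3 conidiation members and 1 oxidative stress member were lower; 9 and 10 conidiation members were without ve-1 iron-free replicates 2 and 1. No ergosterol member was called without either wild-type standard library or ve-1 standard replicate 1, and 1 was without ve-1 standard replicate 2. For sugar transport, 1 member was called without wild-type standard replicate 1 and without each ve-1 standard and wild-type iron-free library. No carotenoid, light and clock or velvet gene was called in edgeR; 1 carotenoid gene, and no light or velvet gene, was lower when adjusted over the list alone.

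Absence of iron in ve-1 lowered 7 of 22 conidiation genes and raised 3 of 3 ergosterol genes, 5 of 11 arg genes of arginine synthesis and 18 of 29 nuo genes of complex I. As groups these passed camera but not with an estimated correlation (adjusted p = 0.4968 for the 2 lists and 0.849 for the arg and nuo families, which were chosen after the data had been seen). con-6 fell from 3720 ± 2110 to 50.8 ± 0.619 CPM and con-10 from 2230 ± 1500 to 45.6 ± 43 (SD, n = 2). cys-14 fell from 350 ± 229 to 4.05 ± 0.41 CPM (log2 fold change -6.42, SE 0.60, adjusted p = 0.00392), ars-1 fell with a log2 fold change of -6.22 (the cys family had 4 of 10 lower and 1 higher and did not pass, adjusted p = 0.275), and sre with -4.48 (SE 0.35). NCU05883 had 0 counts in both iron-free libraries and was at least 1780-fold lower than in standard medium. The perithecial gene poi-2 went from 352 ± 398 to 1.78 ± 2.29 CPM. erg-3 rose from 45.3 ± 8.26 to 550 ± 277 CPM, the thiamine synthesis gene nmt-1 from 542 ± 48.4 to 11600 ± 5550, arg-5 from 32.1 ± 6.2 to 373 ± 99.9 and the formate dehydrogenase gene fdh from 135 ± 24.8 to 3410 ± 3440. cat-2 (log2 fold change -3.22), cat-1 (-2.78) and sod-2 (-1.68) fell. The oxidative stress list had 3 of 8 members lower and 1 higher and did not pass camera (adjusted p = 0.1033). Falls also came in nop-1 (-2.82), frq (-1.14), phy-1 (-0.98) and frh (-0.96). These were the 4 called members of 11 in the light and clock list (4 lower and 1 higher adjusted over the list alone). Of the 65 named calls, 6 held without any 1 library (cys-14, ars-1, sre, ccg-9, NCU05883 and NCU07820). Losses numbered 59 without ve-1 standard replicate 1, 39 without ve-1 iron-free replicate 2, 29 without ve-1 standard replicate 2, 19 without ve-1 iron-free replicate 1, and 6 without each of the wild-type libraries.

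The contrast called 1822 genes, 881 higher and 941 lower, of which 1549 changed at least 2-fold; total-count scaling gave 1418 and 679, with a shift of the median of 0.30. The number called fell to 59 without ve-1 standard replicate 1, to 564 without ve-1 standard replicate 2 and to 371 without ve-1 iron-free replicate 2.

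Complex I genes rose in ve-1 without iron. This contrast shares its 2 ve-1 standard libraries with the fall of these genes in standard medium and with the interaction below, so these results are not independent. Of the 43 respiratory chain genes, 19 rose and none fell (25 and 0 adjusted over the list alone), and 18 of the 19 were nuo genes; nuo10.4 went from 36.7 ± 9.51 to 124 ± 4.73 CPM and nuo29.9 from 71.6 ± 19.4 to 214 ± 18.6 (SD, n = 2). In wild type these genes stayed at 118 ± 11.2 and 123 ± 5.32 CPM, and at 244 ± 34.2 and 210 ± 19.2 CPM. The list was higher in camera (adjusted p = 9.629e-07), the ergosterol list was higher (adjusted p = 0.001629; 3 of 3 members, 3 adjusted over the list alone) and the conidiation list was lower (adjusted p = 0.001629; 7 of 22 members, 8 adjusted over the list alone). With an estimated correlation none held (adjusted p = 0.4968 for each). The level of eas was 51530 and 2485 CPM in the ve-1 iron-free cultures. Without ve-1 standard replicate 1 no respiratory or ergosterol member was called higher and 1 conidiation member was called lower. Without ve-1 iron-free replicate 2 the numbers were 9, 1 and 2, without ve-1 standard replicate 2 they were 12, 2 and 4, and without ve-1 iron-free replicate 1, 12 conidiation members were lower; the conidiation list did not pass without ve-1 iron-free replicate 2 (adjusted p = 0.05116).

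**Figure D4:**
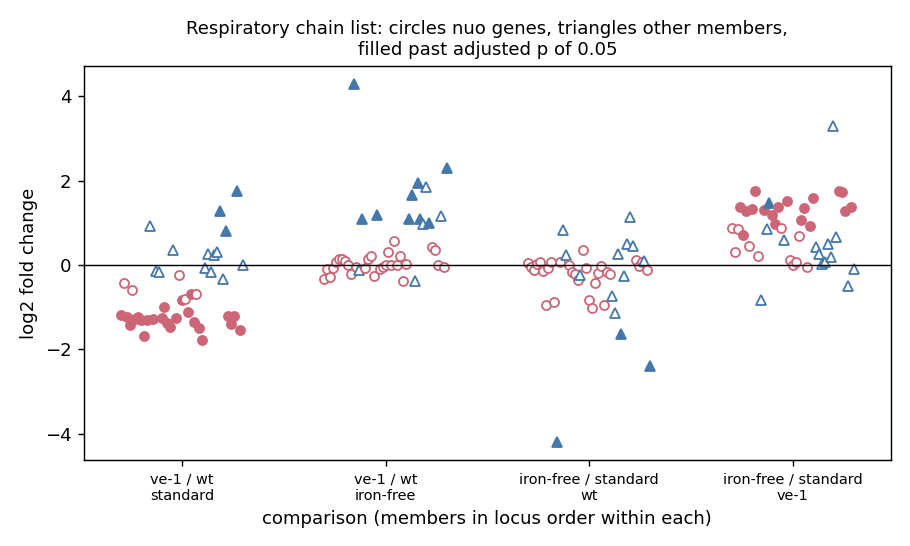
Log2 fold change of each of the 43 respiratory chain genes in the 4 group contrasts, with circles for nuo genes, triangles for other members and filled symbols for genes called over all tested genes. The nuo genes lie mostly below 0 for ve-1 against wild type in standard medium (median -1.25) and above 0 for iron-free against standard medium in ve-1 (median 1.06).

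Across genes, the effect of iron absence in wild type and that in ve-1 had a Pearson r of 0.45 and a Spearman rho of 0.43, with an r of 0.35 without wild-type standard replicate 1 and of 0.39 without ve-1 iron-free replicate 2. Calls in both genotypes numbered 46 higher and 206 lower, where independent lists would share 12.9 and 48, and 5 genes were called in opposite directions, where independent lists would share 58.7.

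The test of the interaction, which asks whether the effect of ve-1 differs between media, called 20 genes, 7 higher and 13 lower. NCU10016 was at 725 ± 323 CPM in ve-1 with iron and below 1 CPM on average in the other 3 groups, and NCU05887 at 557 ± 357 CPM with iron and 0.436 ± 0.0481 without it in ve-1 (SD, n = 2). NCU01057, NCU07610 and NCU10015 were also highest in ve-1 with iron, with ve-1 standard means of 557 ± 267, 1080 ± 338 and 644 ± 276 CPM. Among genes with a higher interaction term, NCU00175 was at 2750 ± 240 CPM in wild type with iron, 15.8 ± 5.22 in ve-1 with iron, 169 ± 56.5 in wild type without iron and 21 ± 7.73 in ve-1 without iron. The respiratory chain list had a higher interaction term than other genes (adjusted p = 9.379e-12, median 1.18), with no member called over all genes and 25 higher adjusted over the list alone. Histones (adjusted p = 0.009039, median 1.00; 4 higher alone) and sugar transport (adjusted p = 0.01806, median 1.96; 1 higher alone) were also higher, and the secondary metabolism backbone list was lower (adjusted p = 0.01806, median -1.05; 2 lower alone), again with no member called over all genes. With an estimated correlation none held, with adjusted p = 0.5275 for the respiratory, histone and sugar lists and 0.5793 for the other. The histone call was lost without wild-type standard replicate 1 (adjusted p = 0.05866). The sugar call was lost there (0.05866) and without ve-1 standard replicate 2 (0.05299), wild-type iron-free replicate 2 (0.1195) and ve-1 iron-free replicate 1 (0.09372), and the secondary metabolism call without wild-type standard replicate 1 (0.06173), wild-type iron-free replicate 2 (0.126) and ve-1 iron-free replicate 1 (0.1326). At an unadjusted p under 0.05, 1650 genes passed.

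The interaction split was 6 higher and 21 lower with total-count scaling, with a shift of the median of -0.23, DESeq2 called 601 genes and limma-voom 2, and 35 were called with no low-count filter. No gene was called without wild-type iron-free replicate 2, ve-1 iron-free replicate 1 or ve-1 iron-free replicate 2 (edgeR), 2 were called without wild-type standard replicate 1, and 3 without wild-type standard replicate 2 or ve-1 standard replicate 1; none of the 10 named genes held without every library in turn.

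Gene families named by symbol stem, 52 of them with at least 5 tested genes, were tested after the data had been seen. None of the 52 passed with an estimated correlation; the lowest adjusted p was 0.399, for the ccg family in wild type without iron. For ve-1 against wild type, mitochondrial protein import genes were higher in both media in camera: in standard medium 7 of 7 tom genes (adjusted p = 0.00547) and 6 of 11 tim genes (adjusted p = 0.0015) rose, and in iron-free medium 5 (adjusted p = 0.0212) and 8 (adjusted p = 2.07e-05); with an estimated correlation the adjusted p of these 4 calls was 0.694 to 0.875. The ham genes of hyphal fusion were lower, with 5 of 9 in standard medium (adjusted p = 0.00795) and 6 in iron-free medium (adjusted p = 3.36e-05). They are also members of the sexual development list, so the 2 calls in iron-free medium overlap. Sulfur genes of the cys family were higher, with 6 of 10 in standard medium (adjusted p = 0.000229) and 3 in iron-free medium (adjusted p = 0.0215). In iron-free medium 5 of 6 acu genes of acetate use (adjusted p = 0.000142) and 9 of 16 tca genes (adjusted p = 0.000228) rose in ve-1, and without iron in wild type 4 acu and 5 tca genes fell (adjusted p = 3.13e-05 for each). The acu and tca families also had a higher interaction term (medians 3.71 and 1.25), with no member called over all genes. All these acu and tca results use the same 2 wild-type iron-free libraries, so they are not independent. For ve-1 against wild type in standard medium neither family passed camera (adjusted p = 0.452 for acu and 0.543 for tca). The arg genes of arginine synthesis were higher without iron in ve-1, with 5 of 11 (adjusted p = 0.0129). With an estimated correlation the families given here had an adjusted p of 0.875 in standard medium, 0.694 to 0.746 in iron-free medium, 0.97 for wild type without iron, 0.849 for ve-1 without iron and 0.928 for the interaction. In camera the acu, tca and tim calls held without any 1 library; the iron-free tom call was lost without ve-1 iron-free replicate 2 (adjusted p = 0.0952), and the iron-free cys call without wild-type iron-free replicate 1 or ve-1 iron-free replicate 2 (highest adjusted p = 0.102).

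Of the genes in the authors' deposited tables that were tested here, every one had the same sign in all 4 contrasts. The share of the deposited genes that was also called was 81.6% and 81.3% for ve-1 against wild type in standard and iron-free medium, and 50.1% and 79.5% for iron-free against standard medium in wild type and in ve-1. With DESeq2 on only the 4 libraries compared, the shares were 99.5%, 99.4%, 99.4% and 99.6% in the same order. Both come from the same libraries, so the overlap is no independent evidence.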

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

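The gene-length correction, and the use of library scaling and of left-out libraries as tests of the respiratory pattern, were chosen only after the result was seen; the scaling, the left-out libraries and the interaction had been planned before the data were examined.

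The test of the interaction asked whether the effect of ve-1 differed between the media, and it picked out 10 named genes and 4 gene lists. Lower in the interaction, that is with an effect of ve-1 that was more negative or less positive without iron, were NCU10016 (log2 interaction -12.09), NCU05887 (-11.54), NCU01057 (-8.67), NCU07610 (-8.29) and NCU10015 (-4.86). Higher in the interaction were NCU01704 (2.69), NCU04644 (3.82), NCU06974 (4.28), NCU00175 (4.44) and NCU04482 (6.61). None of these 10 was called without ve-1 iron-free replicate 1, ve-1 iron-free replicate 2 or wild-type iron-free replicate 2 (edgeR). Without the other libraries the number called of the 10 was 2 (wild-type standard replicate 1, wild-type standard replicate 2, ve-1 standard replicate 1), 6 (ve-1 standard replicate 2) and 4 (wild-type iron-free replicate 1). No explanation of these genes was tested. The lists with a difference between media were the respiratory chain (adjusted p = 9.379e-12), histones (0.009039), sugar transport (0.01806) and secondary metabolism backbone (0.01806), all in camera with a preset correlation. With an estimated correlation none of them passed, with adjusted p = 0.5275 for the first 3 and 0.5793 for the last. The last 3 calls each ended without at least 1 library, with adjusted p = 0.05866 for histones and up to 0.1195 for sugar transport and 0.1326 for secondary metabolism.

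The respiratory chain list had a median log2 interaction of 1.18 over 43 genes. Gene-length bias between libraries is argued against by a median of 1.11 after the length trend was removed. With total-count scaling the median was 0.96. A change of scaling moves all genes nearly alike, here by -0.23 at the median of all genes. It could hardly have ended the pattern, so it was no real test of library scaling. A single deviating culture is argued against by a lowest median of 1.01, without ve-1 iron-free replicate 1, with the camera adjusted p at most 4.9e-08 without any 1 library. What stays open is co-variation of these genes between cultures from a source unrelated to the groups, since the call ended with an estimated correlation (adjusted p = 0.5275) and no member was called alone over all genes in edgeR. The median was 1.21 for the 29 nuo genes and 0.99 for the other 14 members, but 0.19 for the 9 genes of the cyt family. For ve-1 against wild type, the nuo median was -1.25 in standard and 0.01 in iron-free medium. That of the other 14 members was 0.25 and 1.13. The 2 parts thus reached their interaction medians differently, and a shift across the whole list was not shown. A medium-dependent effect of ve-1 on respiratory chain transcripts may be kept only as a hypothesis, found and tested on the same 8 libraries.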

How the results depend on the processing

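The gene-length correction, the velvet list without ve-1, and the correlations, list member counts and runs of neighbours without single libraries were chosen only after the result was seen; the other alternatives were planned. No named call reversed under any alternative, and none that was planned could not be run.

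For iron-free against standard medium in wild type the number of genes called went from 533 to 1290 with total-count scaling, 1249 with DESeq2, 326 with the replicate block within genotype, and 130 (edgeR) and 1088 (DESeq2) with only the 4 libraries compared. For ve-1 against wild type in iron-free medium it went from 1500 to 923 with edgeR on only the 4 libraries compared. For the interaction it went from 20 to 35 with no low-count filter, 601 with DESeq2 and 2 with limma-voom. The cause of these differences was not tested. The fits on 4 used fewer libraries, and DESeq2 on 4 changed the tool as well. Of the 18 list calls, 0 held with an estimated correlation in camera, and with fry 10 held, 8 were lost and 14 other lists passed. Leaving ve-1 out of the velvet list ended its 1 call (adjusted p = 0.1666). DESeq2 on the 4 libraries raised the share of deposited genes also called from 50.1% to 99.4% for the iron effect in wild type and from 79.5% to 99.6% in ve-1. For ve-1 against wild type it rose from 81.6% to 99.5% in standard medium and from 81.3% to 99.4% in iron-free medium.

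With 1 library left out, the numbers called ranged from 104 to 2372 for ve-1 against wild type in standard medium, from 586 to 1496 in iron-free medium, from 7 to 651 and from 59 to 1766 for the iron effect in wild type and in ve-1, and from 0 to 22 for the interaction. The lowest values came without ve-1 standard replicate 1 (104 and 59), ve-1 iron-free replicate 2 (586 and 0), wild-type iron-free replicate 2 (7 and 0) and ve-1 iron-free replicate 1 (0). The correlation across genes ranged from 0.45 to 0.63 for the ve-1 effect and from 0.35 to 0.49 for the iron effect. Over named genes and left-out libraries, 1747 values kept their side of the threshold, 634 no longer passed and 11 newly passed. Of the 235 calls among the 299 named values, 28 no longer passed with limma-voom and 22 with total-count scaling. The number was 20 with the replicate block, 13 with upper-quartile scaling and 7 with the length trend removed. Fits on only the 4 libraries compared, which do not cover the interaction, lost 48 in edgeR and 4 in DESeq2. The replicate block within genotype, which covers only the iron effects and the interaction, lost 25. Thinning to the smallest library (6654585 counts) ended 2 calls among named values; it tests unequal depth only, not what deeper libraries would call.

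The labels do not say whether replicate numbers pair the cultures, and the fit took them as unpaired. Deviations of same-numbered libraries correlated across genes at 0.06 and -0.04 between genotypes (standard and iron-free medium) and at 0.05 and -0.02 between media (wild type and ve-1). A code deposited with each library recurs across media within a genotype, and matA-1 counts of 118 and 0, then 74 and 0, follow it in wild type, so a shared strain stays open. In ve-1 the matA-1 counts were 0 and 403 in standard medium but 1 and 5 in iron-free medium. Contrasts that use the ve-1 iron-free group were therefore not balanced for this transcript. The replicate block called 2034, 1303, 535, 1657 and 21 genes over the 5 contrasts; the block within genotype, besides the 326 above, called 1235 for the iron effect in ve-1 and 14 for the interaction.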

Other observations

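All tests of explanations in this part were chosen only after the result was seen.

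Light and carotenoid genes varied between cultures of each group more than most random gene lists did, at percentiles of 98.1 (wild-type standard), 99.5 (ve-1 standard), 100 (wild-type iron-free) and 87.3 (ve-1 iron-free). In wild type without iron vvd was at 122.6 and 2583 CPM and al-1 at 24.18 and 2052 CPM. The median absolute log2 ratio over the 17 light and carotenoid genes was 0.80, against 0.28 in random gene lists of similar mean; it was 0.48 against 0.27 in wild-type standard, 0.45 against 0.23 in ve-1 standard and 0.49 against 0.34 in ve-1 iron-free cultures. Conidia mixed into the culture with the higher values are argued against by a median log2 ratio of 0.03 over 22 conidiation genes (median absolute deviation 0.89), and eas was at 1253 and 1073 CPM. Mating type acting alike in both genotypes is argued against by ve-1 standard medium, where 17.6% of the 17 genes were higher in the culture without matA-1 counts. A difference between the strains behind the 2 wild-type replicates stays open, since in wild-type standard medium 76.5% were higher in the culture without matA-1 counts, as were 64.7% in wild type without iron. Replicate 2 was the higher culture for 13, 14, 11 and 8 of the 17 genes in wild-type standard, ve-1 standard, wild-type iron-free and ve-1 iron-free groups, so handling shared by replicate number may also contribute. Light at harvest was not tested.

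Genes lower in ve-1 in standard medium often lay side by side. Among 2176 neighbouring pairs more than 1000 bases apart, 103 had both genes lower, where 1000 random gene orders gave a mean of 51.4 and at most 75; these pairs come from the 2258 calls of a contrast that called 104 genes without ve-1 standard replicate 1. Reads shared between overlapping or abutting genes are argued against by that number for the lower genes. For the higher genes the number was 40 in standard medium, against a mean of 33.9 and a 95th percentile of 43, so shared reads stay open there; in iron-free medium it was 24, against a mean of 15.2 and a 95th percentile of 22. Of the 290 genes lower in either medium and in runs of at least 3, 6.2% (18 genes) had at most 3 counts in every ve-1 library. This cannot decide on deleted or diverged stretches in the ve-1 strain. The mutated gene ve-1, with 20, 28, 15 and 80 counts there, would itself not meet that mark. The adjacency was not particular to the ve-1 effect: without iron, 20 such pairs were lower in wild type (mean 5.7, at most 15 in random orders) and 80 in ve-1 (mean 29.1, at most 46). Co-expression of neighbouring genes whatever the contrast therefore stays open and was not tested separately.

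Of the longest runs, 12 genes from NCU05761 to poi-2 were higher in ve-1 in standard medium, with a median log2 fold change of 6.28; none was called without ve-1 standard replicate 1 (median 4.27) and 1 without either wild-type standard library. A run of 6 genes from NCU05883 to NCU05888 had a median of 9.78, and at least 5 were called without any 1 library. In ve-1, 14 genes from pre-2 (NCU05758) to cat-2 (NCU05770) were lower without iron. By locus number NCU05761 lies within this run, and both contrasts use the ve-1 standard libraries, so the 2 runs are not independent. Most or all calls of this run were lost without ve-1 standard replicate 1 or ve-1 iron-free replicate 2, and part of them without ve-1 iron-free replicate 1. Its median log2 fold change was then -5.42, -6.81 and -8.58. In iron-free medium 9 genes from NCU10285 to NCU10572 were lower in ve-1; 0 were called without ve-1 iron-free replicate 2, 1 without ve-1 iron-free replicate 1, 4 without wild-type iron-free replicate 2 and 6 without either ve-1 standard library.

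Pheromone precursor transcripts differed between cultures of a group. ccg-4 was at 161.7 and 0.1509 CPM in the wild-type standard libraries and at 0 and 137 CPM in those of ve-1, and mfa-1 at 7.512 and 15.85 CPM and at 2049 and 8.496 CPM. In both groups ccg-4 was higher in the library with matA-1 counts (118 and 0 in wild type, 0 and 403 in ve-1), and mfa-1 in the other. The replicates of these groups may therefore differ in mating type, which the labels do not give.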
